A study of Mus musculus with 4 samples.

How the data were processed

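Gene expression was measured in liver and duodenum of wild-type mice and of transgenic mice that express a constitutively active form of the aryl hydrocarbon receptor (AhR). AhR is a transcription factor that is normally switched on by ligands such as dioxins; the transgenic form acts without ligand. Per the series design text, tissue of 3 female mice aged 5 to 6 weeks was pooled for each RNA sample, and each pool went onto 1 Affymetrix Mouse Genome 430 2.0 array. Per the labels, total RNA was extracted with Trizol and labelled as biotinylated cRNA, and the mice had free access to standard chow. The 4 arrays were grouped by the genotype and tissue that the labels name, which gives 4 groups of 1 array.

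The deposited values are signal intensity per probe set on a linear scale, made by the authors with MAS5 per the submitters' processing notes. The MAS5 version, scan settings and detection calls are not given in the sources used here. On each array the mean over all 45101 probe sets, with the lowest and highest 2% left out, was 500.0, so the arrays carry a global scaling and every ratio is relative to it. For 18 probe sets of the spiked hybridization controls (bioB, bioC, bioD and cre), the median log2 ratio of transgenic over wild type was -0.68 in liver (SD over probe sets 0.16) and 0.05 in duodenum (SD 0.28). On a scale set by those controls, all liver log2 ratios would be shifted upward by the size of the liver value, which is larger than several of the negative list medians. Those controls report on hybridization and scaling and do not measure tissue RNA, so the shift is a limit and not a correction. The Gapdh 3′/5′ signal ratio, a measure of RNA integrity and of how far labelling reached, was 0.608 in wild-type liver, 0.719 in transgenic liver, 1.03 in wild-type duodenum and 3.07 in transgenic duodenum. The Actb 3′/5′ ratio was 1.51, 1.38, 1.77 and 2.69 in the same order.

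From these values the log2 ratio of transgenic over wild type was computed per gene and tissue, with no further normalization. Signals below a floor of 129.3 were raised to it; the floor is the mean over the 4 arrays of the 40th percentile of all probe sets that are not among the 64 Affymetrix controls. A fold with 1 array at the floor is a bound and is written as at least that size, and genes below the floor on both arrays were left out of that comparison. Probe sets were named through the platform annotation table, with symbols updated by Entrez gene identifier from the RefSeq gene table of GRCm38.p6, which served for names only. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were not listed; those with several symbols were not used to name a gene. This left 18194 genes, each represented by the probe set with the highest mean log2 signal over the 4 arrays. Probe sets whose identifier ends in _x_at, _s_at or _a_at can detect related transcripts, so values for members of close families, such as the Mup, Cyp2c, Cyp3a, Ugt2b, Gstm and defensin genes, are uncertain as to the member.

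The comparisons, the floor, the lists and the rule for named genes were fixed before the data were examined. A gene was counted as higher or lower at 2-fold or more. In addition, 26 gene lists and 22 lists of cell type markers were described by how many members were 1.5-fold or more higher or lower and by the median log2 ratio. The median was ranked among 10000 random gene lists of the same size, matched on mean log2 signal in 20 bins. A list was set apart below the 2.5th or above the 97.5th percentile, as a description of these arrays and not as a test. Lists with fewer than 5 members above the floor got no percentile. The lists hold 701 symbols, of which 621 had a value; the others were not analysed here. Genes named per tissue were the 10 highest and 10 lowest log2 ratios among genes above the floor on both arrays, the 5 largest bounds each way, the 2 highest and 2 lowest members of each list, and always Ahr, Cyp1a1, Cyp1a2, Cyp1b1, Ahrr, Tiparp, Nqo1, Aldh3a1, Cd36 and Fgf21. Across tissues, among genes at 2-fold or more in both, the 10 with the largest smaller log2 ratio were named for shared and for opposed direction. Genes outside this rule are marked as chosen after their values were seen.

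With 1 array per group there is no measure of spread between replicates, and the number of arrays limits the precision of every value. Agreement between probe sets of 1 gene gives a partial view. Among genes called at 2-fold with a second probe set above the floor, the second pointed the same way for 171 of 234 in liver (73.1%) and 607 of 851 in duodenum (71.3%). Where both probe sets had a signal of at least 1000, this was 28 of 29 in liver and 125 of 155 in duodenum. At any signal above the floor, the second reached 1.5-fold the same way for 104 of 234 in liver (44.4%) and 369 of 851 in duodenum (43.4%). Over all genes with a second probe set, called or not, the log2 ratios of the pair correlated at r = 0.35 in liver and 0.33 in duodenum. The procedure was tested on simulated data with noise as wide as the robust SD of the observed log2 ratios, 0.446 in liver and 0.731 in duodenum. Of 100 simulated 2-fold changes per tissue, 48 were called in liver and 47 in duodenum, and of 100 simulated 4-fold changes, 99 and 93. A change set at the 2-fold cut itself is called about as often as not by construction. The changes were placed only in genes well above the floor in wild type, so recovery near the floor was not tried. Unchanged genes were called in 2.29% of 12942 cases in liver and 15.3% of 13923 in duodenum. These rates follow from the simulated SD, which was taken from the observed ratios and so includes any effect of the genotype. They are not measured rates of false calls. The noise was equally wide at all signals, so noise that differs near the floor was not tried. Of 100 unchanged lists, 4 were set apart in liver and 7 in duodenum, counts that the percentile cuts largely fix. Of 20 lists of 15 genes shifted upward by 1.5-fold, 20 were set apart in liver and 15 in duodenum.

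The alternatives tried were 3 other scalings (median log2 ratio set to 0, quantile normalization, and loess on mean log2 signal), 3 other floors (the 25th percentile, the 60th percentile, and none with 16 added before the log), the mean of all probe sets of a gene, omission of the _x_at, _s_at and _a_at probe sets, and thresholds of 1.5-fold and 3-fold. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. No coordinates are given, because the sources used here name no genome build for the array.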

Results

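RNA pools from liver and duodenum of wild-type mice and of mice carrying a constitutively active aryl hydrocarbon receptor (AhR) were each measured on 1 array. The median probe set signal was 176.4 in wild-type liver, 177.1 in transgenic liver, 229.3 in wild-type duodenum and 167.7 in transgenic duodenum. Between 12768 and 13688 genes per array lay above the floor. Across 18661 probe sets above the floor on all arrays, log2 signals correlated at r = 0.950 between the liver arrays and at r = 0.885 between the duodenum arrays; probe sets are not independent replicates. Because each group held 1 array, no difference below has a replicate check, and none carries an error or a test. The differences describe these pools on the MAS5 scale.

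The first comparison addressed which transcripts differed in liver when AhR was constitutively active. Genes of the CYP1 family, cytochromes that oxidise aromatic compounds, were among the genes with the highest ratios. Cyp1b1 was 131-fold higher in transgenic liver, at a signal of 27589.7 against 210.4, and Cyp1a1 was 33.9-fold higher, at 47625.8 against 1403.5. Cyp1a2, already abundant in wild-type liver, was 3.56-fold higher. Ahrr, which encodes a repressor of AhR, was at least 11.3-fold higher, and Tiparp, an ADP-ribosyltransferase gene induced through AhR, was 6.72-fold higher. Nqo1, which encodes a quinone reductase, was 2.36-fold higher.

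Of the 13 AhR target genes measured in liver, 10 were 1.5-fold or more higher, 0 were lower and 3 were neither. The median log2 ratio of the list was 1.37, above all 10000 matched random lists. The lowest members were Xdh, at a log2 ratio of -0.12, and Cyp2s1, at -0.01, while Aldh3a1 stayed near the floor at 99.5 and 151.1. Averaged over its probe sets, Cyp1b1 had a log2 ratio of 4.31 and Ahr one of 0.79. The other probe sets of Cyp1b1 were 41.5-fold and 1.43-fold higher. Ahr itself, of which the transgene encodes an active form, was read by a pair of probe sets whose position relative to the transgene is not known here. They therefore do not check the labels. The brighter probe set of Ahr gave 2019.8 in wild-type and 2274 in transgenic liver, and 2123.3 and 590.2 in duodenum. The dimmer probe set of Ahr gave 324.1 and 860 in liver, 2.65-fold higher in the transgenic pool, and 507.9 and 287.7 in duodenum.

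**Figure D1:**
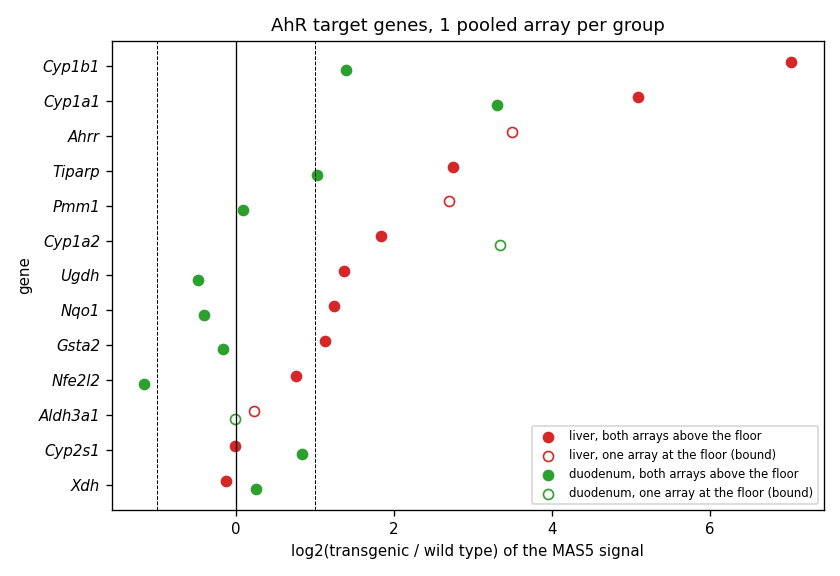
Each point is the log2 ratio of transgenic over wild-type MAS5 signal (horizontal axis) for 1 AhR target gene (vertical axis) in liver (red) or duodenum (green), from 1 pooled array per group; open circles are bounds with at least 1 array at the floor, and dashed lines mark 2-fold. Cyp1b1 lies at 7.03 in liver and 1.39 in duodenum, and Cyp1a1 at 5.08 and 3.30.

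In all, 658 of 13952 genes were 2-fold or more higher in transgenic liver and 500 were lower; 422 and 326 of these were above the floor on both arrays. Besides the AhR targets, the highest ratios among genes above the floor on both arrays belonged to Prom1, a membrane protein of cell protrusions (12.7-fold higher), Cyp2d9, a male-biased hepatic cytochrome (8.63-fold), Ly6d, a surface protein (8.31-fold), Osbpl3, an oxysterol-binding protein (6.57-fold), Fhit, a dinucleotide hydrolase (6.49-fold), Fbxl16, an F-box protein (6.49-fold), and Calml4, a calmodulin-like protein (6.15-fold). Near the floor in wild-type liver were Htra1, a secreted protease (at least 17.4-fold higher), Tff2, a trefoil peptide of mucus (at least 15.9-fold), Ap1m2, an epithelial clathrin adaptor subunit (at least 10.4-fold), and Fxyd3, a regulator of the sodium pump (at least 9.48-fold).

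Among genes above the floor on both arrays, the lowest in transgenic liver were Dct, an enzyme of melanin synthesis (13.5-fold lower), the major urinary protein genes Mup3 and Mup10 (10.2-fold and 9.47-fold lower), Serpina12, which encodes vaspin (8.51-fold), and Sucnr1, the succinate receptor (7.70-fold). Cyp2g1 was 7.03-fold lower, Ppargc1b, a coactivator of mitochondrial genes, 6.85-fold, Cyp4a14, a fatty acid hydroxylase, 6.39-fold, Mvk, mevalonate kinase, 5.28-fold, and the guanylate-binding protein gene Gbp2b 5.20-fold. Genes at the floor in transgenic liver had bounds of at least 15.8-fold lower for Serpina4-ps1, 9.30-fold for the carboxylesterase Ces5a, 7.13-fold for Fank1, 7.06-fold for the acyl-CoA thioesterase Acot1 and 6.87-fold for the steroid dehydrogenase Hsd3b5. Averaging all probe sets of a gene gave log2 ratios of 1.61 for Osbpl3, -1.47 for Mup3, -0.60 for Serpina12, -1.63 for Mvk and -1.20 for Ces5a; without multi-transcript probe sets Ces5a was at -0.47, Serpina4-ps1 at -2.97 and Htra1 at 4.75.

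**Figure D2:**
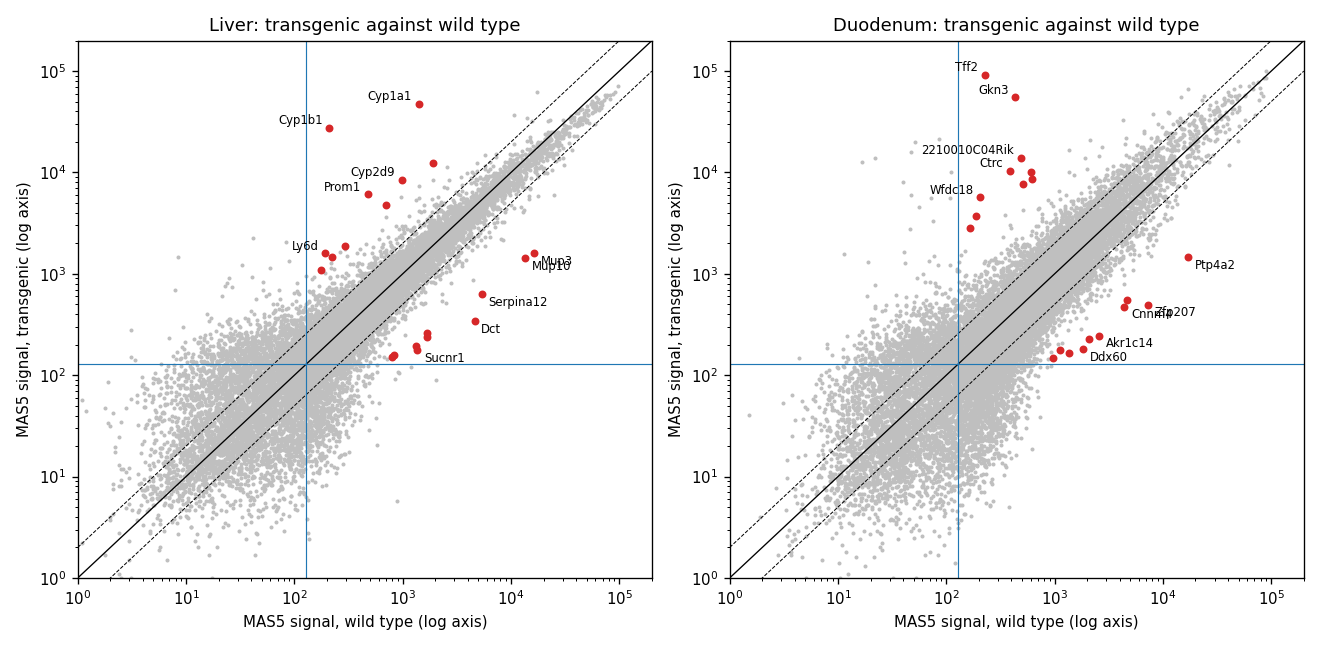
MAS5 signal per gene in the transgenic array (vertical, log axis) against the wild-type array (horizontal, log axis), for liver (left) and duodenum (right); the solid line marks equal signal, dashed lines 2-fold, blue lines the floor of 129.3, and red points the 10 highest and 10 lowest genes above the floor on both arrays. Among the red points, Cyp1b1 and Cyp1a1 lie farthest above the line in liver, and Tff2 and Gkn3 in duodenum.

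Several metabolic gene groups were lower in transgenic liver. Among genes of cholesterol synthesis and SREBP2 regulation, 14 of 19 were 1.5-fold or more lower and 0 higher (median log2 ratio -0.80, below all 10000 matched random lists), with Mvk 5.28-fold and Stard4, a sterol carrier, 2.60-fold lower. Among cytochromes and regulators under the nuclear receptors CAR and PXR, 12 of 19 were lower and 1 was higher (median -0.79, below all matched lists); Cyp3a44 was 3.94-fold and Cyp2c38 3.14-fold lower, while Cyp2c55 was 3.13-fold higher (log2 ratio 0.97 with the floor at the 60th percentile). Of 27 genes of fatty acid oxidation and PPARα regulation, 11 were lower and 0 higher (median -0.43, percentile 0.02), led by Acot1 and Cyp4a14. Fgf21, a hepatic hormone within this list, was 1.34-fold higher. Of 14 genes with female-biased liver expression, 8 were lower and 2 higher (median -0.70, below all matched lists), the higher ones being Prom1 and the sulfotransferase gene Sult1e1 (at least 1.95-fold). This list is not independent of the others. It shares Cyp2b9, Cyp2b13, Cyp3a16 and Cyp3a44 with the CAR and PXR list, Acot3 and Cyp4a14 with the PPARα list, and Sult1e1 with the conjugation enzymes. Its lowest members were Cyp4a14 and Cyp3a44. Were the spiked hybridization controls taken as the scale, only the cholesterol, CAR and PXR, and female-biased lists would keep a median below 0 among the lists that were lower in liver. Those controls do not measure tissue RNA, so this is a limit and not a correction.

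Among 20 bile acid synthesis and transport genes, 6 were lower and 3 higher (median -0.41, percentile 0.10). The uptake transporter Slco1a1 was 2.15-fold lower and the efflux transporter Abcc3 2.14-fold lower, while Cyp8b1, the sterol hydroxylase that directs synthesis towards cholic acid, was 4.39-fold higher. Fatty acid and triglyceride synthesis had 2 lower and 1 higher of 22 (median -0.26, percentile 2.02), with Pklr 1.81-fold (log2 ratio -1.57 over its probe sets) and Fasn 1.77-fold lower and Scd2 2.17-fold higher; with the floor at the 60th percentile the list was at percentile 5.41. Conjugation enzymes split into 8 higher and 8 lower of 32 (median -0.28, percentile 2.27), with the glutathione transferases Gstm3 and Gstm2 3.14-fold and 3.03-fold higher and Ugt2b37 2.13-fold lower. Quantile normalization, loess and omission of multi-transcript probe sets moved this list to percentiles of 3.76, 7.87 and 6.17. Markers of hepatocytes moved with these groups: 2 of 10 were lower, 1 was higher, and their median log2 ratio was -0.50 (percentile 0.58). Under quantile normalization the hepatocyte median was -0.09 and its percentile 23.2, and under loess -0.11 and 17.0.

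Of fatty acid uptake genes, 4 of 14 were higher and 3 lower in transgenic liver (median log2 ratio -0.25, percentile 8.13). Lpl, the lipase that releases fatty acids from lipoproteins, was 3.99-fold higher, and Cd36, a fatty acid translocase, was 1.87-fold higher at 6594.4 against 3526.4. The other probe sets of Cd36 gave 1.46-fold and 1.82-fold. The acyl-CoA synthetase Slc27a5 was 1.66-fold and the liver fatty acid binding protein Fabp1 1.56-fold lower. Both were bright, at 27464.2 and 82577.9 in wild-type liver. The highest signal was 97587.2 on the wild-type and 71556.3 on the transgenic liver array. The dependence on scaling given for hepatocyte markers may therefore hold for these genes too. In the lipid droplet list, 3 of 12 genes were higher and 2 lower (median 0.08, percentile 71.7), with the lipolysis inhibitor G0s2 2.08-fold higher and the droplet coat protein Plin2 1.62-fold lower.

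Cell cycle genes were higher in transgenic liver in 11 of 21 cases and lower in 3 (median log2 ratio 0.66, above all 10000 matched lists). The replication helicase genes Mcm6 and Mcm5 were at least 4.91-fold and 4.68-fold higher, while Tk1, thymidine kinase, was 2.02-fold lower. The mean over probe sets put Mcm6 at a log2 ratio of 0.62, and omission of multi-transcript probe sets put Mcm5 at -0.21. Of 23 cell cycle genes measured in the wild type, 20 were 1.5-fold or more lower in liver than in duodenum (median -1.51). Enterocyte, goblet cell and fibroblast markers were higher in the same transgenic liver pool. The median share of duodenal RNA that abundant duodenal genes would need there was 0.63%. The cell cycle list was a median of 2.85-fold brighter in wild-type duodenum than in wild-type liver, and 1.58-fold higher in transgenic liver. Those values argue against duodenal tissue of the composition on the arrays as the source of the list median. Cells outside that composition were not bounded. Antimicrobial peptide and IL-22 response genes were higher in 6 of 8 cases and lower in 1 (median 0.87, percentile 99.98). In the wild type, 8 of 11 measured members were lower in liver than in duodenum (median -4.82), and enterocyte and goblet cell markers were higher in the same liver pool. Lyz1, lysozyme, was 5.24-fold higher on a probe set that can bind a close paralog, and at a log2 ratio of 0.86 without it; the acute phase gene Saa1 was 2.98-fold higher. Heat shock genes were higher in 2 of 12 cases and lower in 0 (median 0.21, percentile 98.0), led by Hspa1b, 2.20-fold higher; 4 of the alternatives put this list between percentiles 91.3 and 96.4. MHC class II genes were lower in 2 of 7 cases and higher in 0 (median -0.54, percentile 0.18), with H2-Ab1 2.45-fold lower.

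Marker lists showed connective tissue and intestinal transcripts at higher levels in transgenic liver. All 11 markers of stellate cells and fibroblasts were 1.5-fold or more higher (median log2 ratio 1.37, above all matched lists), including the collagen gene Col3a1 (5.89-fold; log2 ratio 1.66 without multi-transcript probe sets) and the proteoglycan gene Lum (4.28-fold). Enterocyte markers were higher in 5 of 8 cases (median 0.87, percentile 99.9), with the peptide transporter Slc15a1 at least 2.36-fold and lactase, Lct, at least 2.28-fold higher, and log2 ratios of 0.20 and 0.15 with the floor at the 60th percentile. Goblet cell markers were higher in 3 of 6 cases (median 0.69, percentile 99.96), with the trefoil peptide Tff3 2.89-fold higher, and Zg16 4.40-fold higher on a probe set without which its log2 ratio was -0.04. Genes of nutrient digestion and absorption, which share members with the enterocyte markers, were higher in 5 of 17 cases and lower in 3 (median 0.37, percentile 98.9), but reached percentile 70.5 with the floor at the 60th percentile. Markers of Kupffer cells and macrophages were lower in 2 of 11 cases and higher in 1 (median -0.33, percentile 1.31), with percentiles of 4.67 and 20.5 under the mean of probe sets and without multi-transcript probe sets. Exocrine pancreas markers in liver had a median of -0.31 (percentile 6.05), but one of 0.54 (percentile 99.03) under the mean of probe sets. Endothelial markers had a median of -0.08 (percentile 29.6), with 1 of 10 higher and 1 lower.

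**Figure D3:**
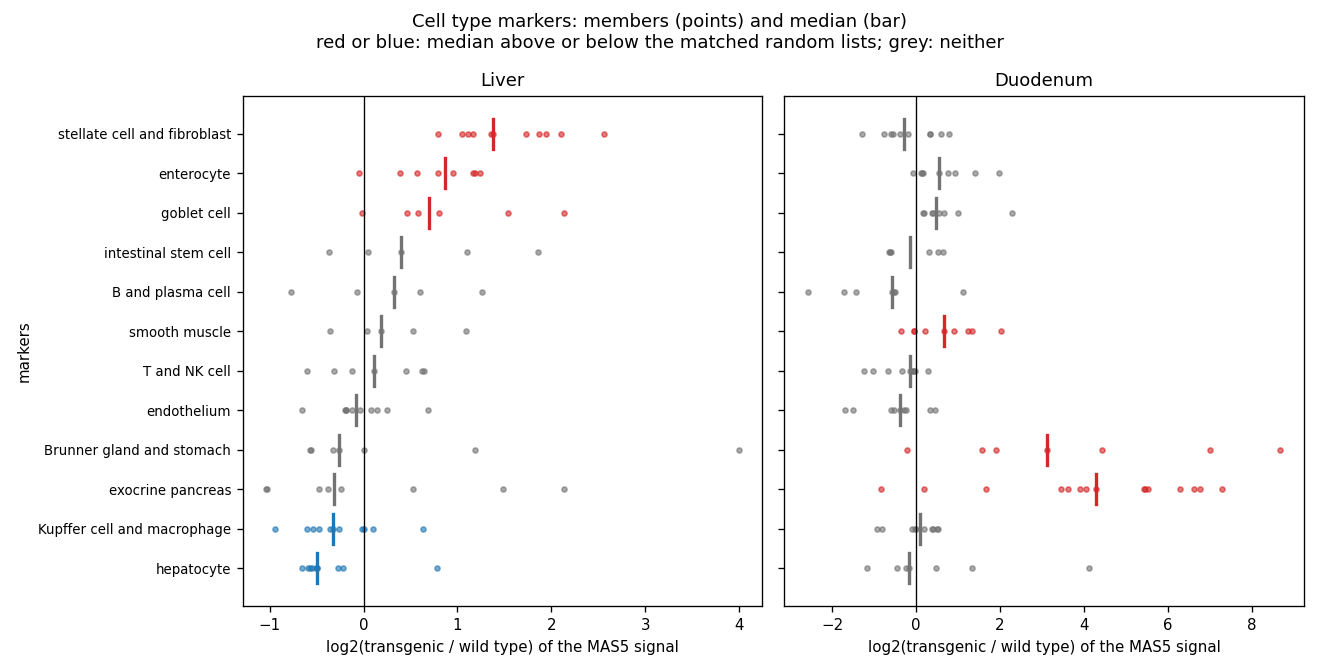
Log2 ratio of transgenic over wild-type MAS5 signal (horizontal axis) for members of the marker lists with at least 5 members above the floor in both tissues (vertical axis), in liver (left) and duodenum (right); points are genes, bars are list medians, and red or blue marks medians above or below the matched random lists. Stellate cell and fibroblast markers have a median of 1.37 in liver, and exocrine pancreas markers one of 4.30 in duodenum.

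In duodenum, stomach, gland and pancreas transcripts were among those with the highest ratios. Tff2, the trefoil peptide of Brunner glands and gastric mucus, was 409-fold higher in the transgenic pool, at 92301.5 against 225.8, and the gastrokine gene Gkn3 was 129-fold higher. Pancreatic enzyme genes were also higher: the elastase gene Cela2a was at least 108-fold, the chymotrypsinogen gene Ctrb1 at least 155-fold and the carboxypeptidase gene Cpa1 at least 98.0-fold higher, and Ctrc, Cel, Cela3b and the trypsinogen gene Prss2 were 27.1-fold, 19.7-fold, 16.7-fold and 15.1-fold higher; over their probe sets Cela3b and Prss2 had log2 ratios of 7.03 and 6.19. Of the 15 exocrine pancreas markers, 13 were higher and 1 lower (median log2 ratio 4.30, above all matched lists; 5.44 with the mean of probe sets), and 8 of the 15 were already above the floor in wild-type duodenum. Of 7 Brunner gland and stomach markers, 6 were higher and 0 lower (median 3.11, above all matched lists; 2.45 under quantile normalization, 2.07 with the floor at the 60th percentile and 2.29 with none), while Atp4b, of the gastric proton pump, was 1.15-fold lower. Whether the dissected piece lay nearer the stomach in the transgenic pool was not tested, so the values of Tff2, Gkn3 and this list do not separate that from genotype.

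AhR targets in duodenum were higher in 5 of 12 cases and lower in 1, and the list median of 0.16 lay at percentile 70.4. Cyp1a1 was 9.86-fold higher, at 20795.8 against 2109.5, and Cyp1a2 at least 10.2-fold higher. For Cyp1b1 the brightest probe set was 2.62-fold higher, but another was 1.99-fold lower and the remaining one was below the floor on both arrays. That lower probe set also changed least in liver, at 1.43-fold higher against 131-fold and 41.5-fold for the others. For Tiparp the brightest was 2.04-fold higher and the others 1.86-fold and 1.05-fold lower. Averaged over probe sets, Cyp1b1 was at a log2 ratio of 0.28 and Tiparp at 0.02, and with the floor at the 60th percentile Cyp1b1 was at 0.38. Nqo1 was 1.33-fold lower, Nfe2l2, a regulator of the oxidative stress response, was 2.24-fold lower, and Ahrr was below the floor on both arrays. Cd36 was 1.30-fold lower, with its other probe sets 1.85-fold and 2.18-fold lower, and Fgf21 was below the floor.

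In all, 1287 of 14721 genes were 2-fold or more higher in transgenic duodenum and 1632 lower. This split depended on the scaling: quantile normalization gave 1469 higher and 1026 lower, and loess 1374 and 1117. Further genes with high ratios, some above those of the pancreatic enzymes, were the antibacterial recognition protein Pglyrp1 (13.9-fold), the protease inhibitor family member Wfdc18 (28.0-fold), the transport protein Ttr (17.3-fold; log2 ratio 2.00 over its probe sets), 2210010C04Rik (28.6-fold), 2310057J18Rik (at least 123-fold) and a Paneth cell defensin probe set named Defa31 (at least 164-fold), which other defensin transcripts can also bind. Lowest among genes above the floor on both arrays were Zfp207, a zinc finger protein (14.6-fold lower), the phosphatase Ptp4a2 (11.7-fold), the steroid-metabolising Akr1c14 (10.5-fold), the helicase Ddx60 (10.1-fold) and the exchange factor Net1 (9.09-fold). Nadk2, a mitochondrial NAD kinase, was 8.34-fold, Rp2 8.06-fold, Zfp386 6.51-fold and Chac2 6.37-fold lower. Cnnm4 was 9.29-fold lower on its brightest probe set, but its probe sets disagreed in direction. Bounds of at least 7.11-fold for Cdc42bpa, 6.52-fold for Eps15l1, 5.73-fold for Ssc4d, 5.64-fold for Castor1 and 5.49-fold for Ntmt1 were the largest of the downward bounds. Averaged over probe sets, the log2 ratios were -1.79 for Zfp207, -1.24 for Ptp4a2, -1.41 for Ddx60, -1.95 for Nadk2, -2.05 for Rp2, -1.66 for Zfp386, -0.78 for Cnnm4, -0.45 for Eps15l1 and -1.23 for Ntmt1.

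MHC class II genes, which present antigen to helper T cells, were higher in transgenic duodenum in 5 of 7 cases and lower in 0 (median log2 ratio 2.22, above all matched lists). The invariant chain gene Cd74 was 7.58-fold and H2-Ab1 7.23-fold higher, while Ciita, the transactivator of these genes, was 1.31-fold lower. Averaged over probe sets, H2-Ab1 had a log2 ratio of 1.97 and Ciita one of 0.62. Without multi-transcript probe sets the list median was 0.84, with too few members for a percentile. Cell cycle genes were higher in 11 of 24 cases and lower in 2 (median 0.56, percentile 99.8), with Mcm2 4.32-fold and the cyclin gene Ccnd1 2.98-fold higher and the replication clamp gene Pcna 2.11-fold lower; Mcm2 had a log2 ratio of 1.04 without multi-transcript probe sets, and Ccnd1 one of 2.28 over its probe sets. Conjugation enzymes were lower in 11 of 30 cases and higher in 3 (median -0.31, percentile 0.56), with the sulfotransferase Sult1d1 3.33-fold lower and Gstk1 3.34-fold higher; without multi-transcript probe sets the percentile was 17.995. Smooth muscle markers were higher in 5 of 9 cases and lower in 0 (median 0.66, percentile 98.8), led by Cnn1, calponin, 4.07-fold higher; without multi-transcript probe sets the median was -0.05. Enteroendocrine markers were higher in 5 of 10 cases and lower in 2 (median 0.69, percentile 99.5), led by the secretin gene Sct, 2.37-fold higher, and lay at percentiles of 95.5 under quantile normalization and 96.5 under loess. The Gapdh 3′/5′ ratio of 3.07 in transgenic against 1.03 in wild-type duodenum accompanies all duodenum values, and no array could be left out.

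**Figure D4:**
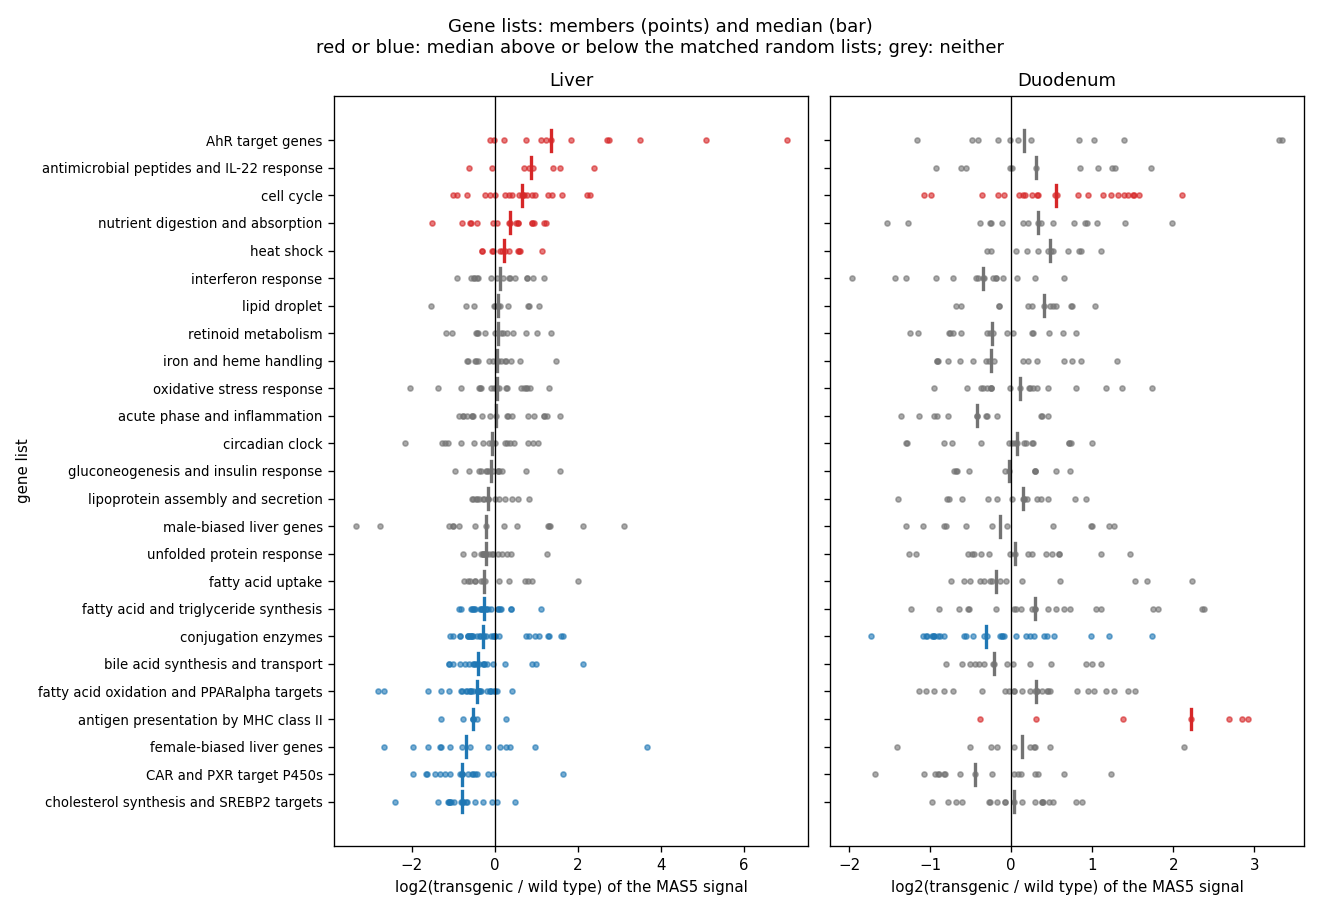
Log2 ratio of transgenic over wild-type MAS5 signal (horizontal axis) for members of the gene lists with at least 5 members above the floor in both tissues (vertical axis), in liver (left) and duodenum (right); points are genes, bars are list medians, and red or blue marks medians above or below the matched random lists. Cholesterol synthesis has a median of -0.80 in liver and 0.04 in duodenum, and MHC class II genes of -0.54 and 2.22.

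The next comparison set the liver ratios beside the duodenum ratios; these share no array. Of 12996 genes measured in both, 109 were 2-fold or more higher in both tissues, where independent lists would share 54.3, and 61 were lower in both, against 51.1. Higher in liver and lower in duodenum were 53 genes, against 69.1, and lower in liver and higher in duodenum were 36, against 40.1. Across 10133 genes above the floor on all arrays, the log2 ratios correlated at Pearson's r = 0.10 and Spearman's rho = 0.10; genes are not independent replicates. Ranked by the smaller of the ratios in both tissues, the genes that led the shared upward ratios were Tff2, Cyp1a1 and Cyp1a2, Prom1 (12.7-fold in liver, 4.38-fold in duodenum), Acta1, skeletal muscle actin (at least 5.31-fold and 35.0-fold), Fxyd3 (at least 9.48-fold and 4.74-fold), Serinc2 (at least 5.04-fold and 4.46-fold) and Amn, a vitamin uptake receptor subunit of epithelia (3.67-fold and 5.37-fold). Of 21 genes with a signal of at least 10000 in both duodenum arrays and below the floor in wild-type liver, 15 were above it in transgenic liver. Cyp1a1 and Cyp1a2 were brighter in transgenic liver (47625.8 and 62037.9) than in transgenic duodenum (20795.8 and 1315.4). For these genes that argues against intestinal RNA as the source of the liver ratio. Tff2 is taken up further below. How far intestinal RNA in that liver pool adds to the remaining shared upward genes was not tested. Slitrk2 and Mpp2 were lower in both, each by at least 3.67-fold in liver and 3.76-fold in duodenum, with Slitrk2 at a log2 ratio of -0.79 in liver over its probe sets. With the floor at the 60th percentile both were under 2-fold, Slitrk2 at -0.87 and -0.89 and Mpp2 at -0.83 and -0.87. Among cell cycle genes, 8 were 1.5-fold or more higher in both tissues and 0 lower in both; named after their values were seen, they were Ccna2, Mcm2, Mcm4, Mcm5, Mcm6, Mcm7, Cdc20 and Cdkn1a.

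Wild-type liver was set against wild-type duodenum to check the tissue labels. Hepatocyte markers were higher in liver in 9 of 10 cases (median log2 ratio of liver over duodenum 8.18), and the fibrinogen gene Fgb gave a signal of 90935.5 in liver and 23.9 in duodenum. All 9 enterocyte markers (median -6.80) and all 8 goblet cell markers (median -5.92) were lower in liver; lactase, Lct, gave 19549.1 in duodenum and 115.2 in liver. In all, 2034 of 14919 genes were 2-fold or more higher in liver and 2761 lower. The excess of lower genes depended on the scaling: with the median log2 ratio set to 0 the counts were 2373 and 2291, under quantile normalization 2348 and 2344, and under loess 2357 and 2197. The median log2 ratio over all genes was -0.13, and the other scalings shifted it upward by 0.11 to 0.13.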

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

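The tests in this part were all chosen only after the results they bear on were seen. Genes whose log2 ratios pointed in opposite directions in liver and duodenum, with at least 2-fold each way, drew attention; the difference between tissues was not tested, since each group held 1 array. The liver minus duodenum difference in log2 ratio was -3.96 for Ptpn23, -3.78 for Zbtb10, -3.62 for Khsrp, -3.25 for Peg3 and -4.50 for Ercc1, all lower in transgenic liver and higher in transgenic duodenum. It was 4.27 for Pcp4l1, 3.24 for Oprm1, 3.31 for Fmo4, 3.67 for Clstn3 and 3.19 for Wfdc1, all higher in liver and lower in duodenum. Each of these 10 genes fell under 2-fold in at least 1 tissue under an alternative. Without multi-transcript probe sets, Khsrp was at -0.04 in liver, and Ercc1 at -0.20 in liver and 0.36 in duodenum. Over the mean of probe sets, Peg3 was at -0.04 in liver, Khsrp at -0.82 in liver, Ercc1 at -0.54 in liver and 0.74 in duodenum, and Zbtb10 at -0.99 in liver and 0.69 in duodenum. With the floor at the 60th percentile, Ptpn23 was at -0.98 in liver and 0.90 in duodenum, Zbtb10 at -0.96 and 0.73, Oprm1 at 0.55 and -0.61, and Wfdc1 at 0.64 and -0.46. With that floor Fmo4 was at 0.71 in liver, and Pcp4l1 and Clstn3 at -0.61 and -0.65 in duodenum. For MHC class II genes, lower as a list in liver and higher in duodenum, the median difference over the 7 members was -2.99, also untested.

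Probe sets not named here with exactly 1 gene carried signal as well: 219 of 5342 above the floor were 2-fold or more higher and 246 lower in transgenic liver, and 234 of 6186 were higher and 1040 lower in transgenic duodenum. The 5′ probe set for 18S ribosomal RNA, a control outside the gene comparisons, was 11.2-fold brighter in wild-type than in transgenic duodenum (3206.2 against 287.5).

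Pancreas markers were higher in the transgenic duodenum, with a median log2 ratio of 4.30. The tables argue against loss of other RNA that raised the transcripts of all secretory cell types alike, because goblet, Paneth and enteroendocrine markers together had a median of 0.54. Brunner gland and stomach markers were left out of that median, and 6 of 7 of them were higher (median 3.11). Within the Paneth list, the highest member had a log2 ratio of 7.355. An increase limited to some secretory cells was therefore not addressed. Pancreas tissue in the transgenic duodenum pool cannot be told apart from an effect of the genotype: 12 of the 15 markers were 4-fold or more higher, but this count restates the pattern and favours neither. The other 3 already had signal in wild-type duodenum: Zg16 62234.1, Reg1 50872.1 and Clps 2979.2, with Zg16 a goblet cell marker too and Reg1 1.78-fold lower in the transgenic pool. After Zg16 and Reg1, the most abundant markers in that pool were Ctrb1 (20057.7), Cela1 (16599.6) and Cela2a (14013.5). An effect of the genotype stays open as untested, and so does a piece of tissue nearer the stomach for Tff2, Gkn3 and the other Brunner gland and stomach markers.

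Fibroblast and stellate cell markers were higher in the transgenic liver, with a median log2 ratio of 1.37 over 11 markers, all also above the floor in wild-type liver. A lower share of hepatocytes would raise the other cell types alike, but 0 of 21 endothelial and macrophage markers were as high as the lowest stellate marker. The tables also argue against duodenal tissue of the composition on the duodenum arrays: 7 of the 11 markers were brighter in transgenic liver than on either duodenum array, and the other 4 would need a share of at least 32.2%, so that 11 of 11 lie over 10 times the median share of 0.63% for abundant duodenal genes. Intestinal connective tissue without the other duodenal cells cannot be told apart from a change in liver, because only 2 of the markers, Reln (2.25-fold higher) and Colec11 (2.06-fold), are over 2-fold brighter in wild-type liver than on both duodenum arrays, and 2 are too few to decide. An effect of the genotype stays open as untested.

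Intestinal epithelial transcripts were higher in the transgenic liver. Of 21 genes with a signal of at least 10000 in both duodenum arrays and below the floor in wild-type liver, 71.4% were above it in transgenic liver, against 9.8% of 2790 genes below it in wild-type liver and in both duodenum arrays, which is consistent with a trace of intestinal mucosa in the pool, at a median share of 0.63%. In the reverse direction, 1 of 7 such genes was above the floor only in wild-type liver. The 9.8% is not a matched background for the 71.4%, because the 2790 genes had to be below the floor on every other array. That trace does not reach the level of Tff2, which would need 2.14% of transgenic duodenum RNA, a share that 0 of the 21 genes needed. Carry-over of the transgenic duodenum RNA itself cannot be told apart from other mucosa: of 10 genes picked for a signal of at least 5000 in that pool and 16-fold over wild-type duodenum, most of them pancreatic but also Tff2 and the Paneth cell defensin Defa31, 3 were above the floor: Tff2, Wfdc18 and 2310057J18Rik. The other 7 stayed below it, among them Ctrb1 (20.1 against 19.5 in wild-type liver), Cpa1 (15.3 against 17.2), Ctrl (94.3 against 98.5) and Defa31 (36.7 against 31), which goes against carry-over of that pool, while Pnliprp1 gave 61.7 against 12.3, and values below the floor do not decide. The 21 did not move alike: Rbp2, with 62720.5 in transgenic duodenum, gave 158.2 in transgenic liver against 25.2 in wild type, while Fcgbp, with 35688.7, gave 96.6 against 97.3, and an effect of the genotype stays open as untested.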

How the results depend on the processing

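Across 3 scalings, 3 floors, the mean of probe sets, omission of the _x_at, _s_at and _a_at probe sets, and the 1.5-fold and 3-fold thresholds, counts and AhR target medians stayed within 1.5 times, or within 1.5-fold, of the reported value in 95 cases and moved further in 49. Other list medians stayed in 730 cases, moved in 15 and reversed in 1; named genes stayed in 3028, moved in 280 and reversed in 10. No analysis that pairs the arrays by tissue was run, and each group has 1 array. The liver counts of 658 higher and 500 lower became 1328 and 1155 with the floor at the 25th percentile, 292 and 189 at the 60th, 1682 and 1470 with no floor, 153 and 75 at 3-fold, and 1888 and 1687 at 1.5-fold. The duodenum count of 1287 higher became 2123 with no floor, 352 at 3-fold and 2831 at 1.5-fold. The duodenum count of 1632 lower became 1026 under quantile normalization, 2645 and 671 with the floor at the 25th and 60th percentile, 2931 with no floor, 302 at 3-fold and 3815 at 1.5-fold. Genes higher in both tissues (109) numbered 234, 40 and 301 with those floors in the same order, 71 with the mean of probe sets, and 11 and 474 at 3-fold and 1.5-fold. Genes lower in both (61) numbered 37 under quantile normalization, 255, 7 and 355 with those floors, and 3 and 477 at 3-fold and 1.5-fold. Genes higher in liver and lower in duodenum (53) numbered 30 under quantile normalization, 31 under loess, 185, 8 and 288 with those floors, and 2 and 372 at 3-fold and 1.5-fold. Genes lower in liver and higher in duodenum (36) numbered 124, 11 and 197 with those floors, 22 with the mean of probe sets, and 2 and 256 at 3-fold and 1.5-fold. Genes lower in wild-type liver than in duodenum (2761) numbered 1766 with the floor at the 60th percentile. Gene lists set apart downward in duodenum numbered 1 as reported, 3 under quantile normalization, 2 under loess and 0 without multi-transcript probe sets, which also left 1 of 2 set apart upward. The upward list lost there, MHC class II genes, had too few members left for a percentile. A lower floor or threshold admits more genes by construction; the cause of the other shifts was not tested. Counted as reversed were, without multi-transcript probe sets, the smooth muscle median in duodenum (-0.0513), Mcm5 (-0.21) and Zg16 (-0.0408) in liver, and Vldlr (-0.0777), Alad (-0.57) and Hspa1b (-0.14) in duodenum. With the mean of probe sets, Prss2 (1.13) and Epcam (0.81) in liver and Gclm (-0.0685), Arntl (0.043) and Ighm (-0.63) in duodenum were counted as reversed. These use other probe sets of the same genes, and the cause was not tested. Among other sign changes, counted as moved, were Marco in liver (-0.61 to 0.90) and Fmo2 in duodenum (0.48 to -1.03) with that mean. So were 2 liver list medians: T and NK cells with the floor at the 60th percentile (0.11 to -0.60), and ileum without multi-transcript probe sets (0.31 to -0.38). The acute phase median in liver, counted as stayed, went from 0.02 to -0.39 without multi-transcript probe sets. Quantile normalization moved the median of all duodenum genes by 0.13. Signal over background limits genes near the floor of 129.3: 58.3% of probe sets lay above it on each liver array, 65.1% in wild-type and 57.2% in transgenic duodenum.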

Other observations

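In transgenic liver the metal-binding metallothionein genes Mt2 and Mt1 were 4.11-fold and 2.60-fold lower, while the extracellular antioxidant gene Gpx3 was at least 2.47-fold higher (log2 ratio 0.26 with the floor at the 60th percentile). Among retinoid genes, Cyp26b1, which degrades retinoic acid, was 2.56-fold and Lrat, which esterifies retinol, 2.01-fold higher, while Rdh11 and Aldh1a1 were 2.28-fold and 2.05-fold lower. Of the circadian genes, the clock output factor Dbp was 2.40-fold lower and Ciart at least 4.47-fold lower, while Arntl was 2.05-fold higher, but at a log2 ratio of 0.05 with the floor at the 60th percentile. Igfbp1, an insulin-repressed secreted protein, was 2.96-fold higher, and the transferrin receptor gene Tfrc was 2.78-fold higher. The chaperone gene Creld2 was 2.38-fold higher in liver and 2.77-fold higher in duodenum. Male-biased liver genes went both ways, with 5 of 15 higher and 6 lower: Cyp2d9 and Cyp8b1 were 8.63-fold and 4.39-fold higher, and Mup3 and Hsd3b5 10.2-fold and at least 6.87-fold lower. That list lay at percentile 9.81, and at 1.72 with the floor at the 25th percentile.

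In transgenic duodenum, 8 of 22 genes of fatty acid and triglyceride synthesis were 1.5-fold or more higher and 3 lower (percentile 92.5), with the desaturase Fads2 5.20-fold and the fatty acid synthase gene Fasn 5.10-fold higher and Scd1 2.35-fold lower; over its probe sets Fads2 had a log2 ratio of 1.46. All 6 mast cell markers were lower (median log2 ratio -0.89, percentile 8.55), including the protease Mcpt2, 2.15-fold, although the probe sets of Kit disagreed in direction and averaged -0.05, and Tpsb2 was at -0.18 over its probe sets and at -0.02 with the floor at the 60th percentile. The B cell genes Ms4a1 and Cd79b were 5.96-fold and at least 3.29-fold lower, with Ms4a1 at a log2 ratio of -1.84 over its probe sets and Cd79b at -0.67 with the floor at the 60th percentile. The B and plasma cell list as a whole had a median of -0.57 (percentile 6.24), and stood at percentiles of 0.745 under quantile normalization and 0.53 under loess. The cytotoxic granule genes Gzmb and Gzma were 2.37-fold and 2.04-fold lower. The interferon response list had 5 of 16 genes lower and 1 higher (median -0.34, percentile 19.85). Its lowest members were Stat2, 3.91-fold lower, and Gbp3, at least 2.69-fold lower, with Stat2 at -1.21 over its probe sets. With the floor at the 60th percentile Stat2 was at -0.93 and Gbp3 at -0.39. Cytochromes under CAR and PXR were lower in 8 of 17 cases and higher in 2 (median -0.45, percentile 4.04; 0.89 under quantile normalization and 1.58 under loess), with Cyp2c65 3.21-fold lower and Cyp2b10 2.35-fold higher. The peptidase Anpep was 3.95-fold higher and the trypsinogen-activating protease Tmprss15 2.90-fold lower, and the glutathione peroxidase Gpx2 was 3.35-fold higher. The antimicrobial lectin Reg3b was 3.32-fold higher.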
